A study of Mus musculus with 10 samples.

How the data were processed

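RNA-seq of mouse bone marrow-derived dendritic cells was analysed in 6 libraries, 3 titled activated and 3 non-activated, of a series of 10 samples. The other 4 samples, 2 per group, were ATAC-seq and were not analysed here, so nothing is said of chromatin. Per the labels' protocols, libraries were made from 200 ng of total RNA with a NEBNext Ultra kit and sequenced as single reads of 60 nt on an Illumina HiSeq instrument. The protocols do not say that the kit kept strand, so reads of a gene and of an overlapping gene on the other strand cannot be told apart.

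The deposited files are gene tables in the layout of RSEM, which assigns reads that match several genes or transcripts in fractions. Per the file headers, the authors deposited an expected count for each gene, along with TPM (scaled by effective length and library size) and FPKM values, and a gene length and effective length. The expected counts were used for the main tests, the deposited TPM for an alternative, and the deposited FPKM was not used in a test. The tables list 41813 mouse Ensembl genes, although the files carry the name of a human build; the submitters' processing notes name GRCm38, the mouse build. Those notes also name CASAVA, bcl2fastq, FastQC, cutadapt, limma, BWA, SAMtools, HOMER and MACS2, with no version or role, and the aligner of the RNA reads is not given in the sources used here. Symbols were matched by gene ID to 41597 genes; genes without a symbol took at most 0.05% of the counts of a library. Coordinates are those of RefSeq on GRCm38.p6, the same build, joined by Ensembl ID or symbol.

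Summed expected counts were 27404937, 21338012 and 24958692 in activated replicates 1 to 3 and 25789923, 23602084 and 23441520 in the non-activated ones, and between 18803 and 19604 genes had a count above 0. Mitochondrially encoded RNA took 1.80% to 2.12% of counts in activated and 2.20% to 2.56% in non-activated libraries. At this depth the common biological coefficient of variation was 16.9%, so the spread between libraries and not the counting error limited all but the low genes. Intervals on counts pool the libraries of a group and leave out the spread between libraries. They cover counting error only, and not all of it, since PCR copies are not told apart. Log2 CPM correlated at 0.976 to 0.986 within groups and 0.945 to 0.960 between them, and no pair of libraries agreed within sampling noise (chi-square over degrees of freedom of 15.2 to 71.4). The labels do not say whether replicates were separate animals or cultures, so p-values measure only the spread between these samples.

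Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (13946 genes kept), TMM factors, glmQLFit and glmQLFTest with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the root of the F statistic. CPM values are TMM-scaled unless called raw. Gene lists, 31 in number, were tested with limma 3.58.1's camera (two-sided, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted over the 30 lists with at least 3 tested members; camera with an estimated correlation and fry were alternatives. With the estimated correlation 0 of the 30 lists passed, the lowest adjusted p being 0.402, and 1 had an unadjusted p under 0.05. That form also rests on the few residual degrees of freedom of 6 libraries, whereas the preset form does not. The dendritic cell identity list, with an estimated correlation of -0.001, still went from an unadjusted camera p of 0.0314 to 0.0831. Failure in that form alone therefore does not show that correlation accounts for a call. Nor is correlation set aside as a cause. The called lists had estimated correlations from 0.044 (costimulation) to 0.786 (type I interferon), all above the preset 0.01. How much of the loss came from correlation was not tested. With the preset correlation 10 lists had an unadjusted camera p under 0.05. The lists covered markers of T cells, activated helper T cells, B cells, NK cells, neutrophils, macrophages and monocytes, and mast cells and basophils, as well as dendritic cell identity, maturation, presentation, costimulation, cytokine, chemokine, receptor, signalling, metabolic, cytoskeletal, cell cycle, chromatin, apoptosis and RNA quality genes.

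Sample titles share replicate numbers across groups. Deviations from the group means correlated at 0.40, 0.31 and 0.19 for libraries with the same number and at -0.31 to 0.04 for the others, so the numbers pair the samples by these data; the labels do not say what a number marks. The model without a block was fixed as the main one, and the paired model with the replicate number as a block was an alternative.

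Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took 14 genes in advance, the 12 highest and 12 lowest log2 fold changes among genes past the threshold with a mean CPM of at least 5 and groups that did not overlap (chance puts 10% of unchanged genes in that state with 3 against 3). It also took per list the 4 members with the smallest adjusted p, or the 2 most abundant where none passed. It gave 137 genes, some of which are not reported here. Another 55, among them Tnfrsf9, Osm, Rel, Map3k14, Actb, Actg1, the members of small list counts and of gene families, were named after their values were seen, as were the T cell receptor genes and the replicate 1 genes. Of the 192 genes, 44 had a fractional expected count in all 6 libraries (Cd40, Cd274, Icam1, Irf1, Gbp5, Tgtp2, Igtp, Il2ra, Ebi3, Xcr1, Csf2rb and Cenpa among them) and 41 overlap another annotated gene (Dll4, Il6, Il27, Adamts4, Erbb2, Ccl3, Cd274 and Bcl2l1 among them), and their values are uncertain to the extent that reads were shared.

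Alternatives were DESeq2 1.42.0, limma-voom, library totals or upper-quartile factors in place of TMM, no filter or a CPM of at least 1 in at least 3 libraries, limma on log2 of the deposited TPM plus 1 or plus 0.1, stricter thresholds, leaving out the T cell list genes, leaving out each library, and, added later, leaving out both replicate 1 libraries. The edgeR steps were tested on 10 simulated sets drawn with the means and library sizes of this comparison, 13946 genes each with 200 changed. It recovered 26.0% of genes changed 1.5-fold, 64.7% of those changed 2-fold and 90.7% of those changed 4-fold, none in the wrong direction. These rates are for 200 changed genes, a smaller share than the 27.6% that passed in the real comparison, and need not carry over to it. Of 1292 calls in these sets 8.9% were false, above the nominal rate. The list test was run on 1 further set with genes drawn independently, so it does not bear on correlated genes. It called the 1 shifted list and none of the lists without a member in common, the others not being counted. Figures were drawn with matplotlib 3.10.9.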

Results

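The series measured messenger RNA and open chromatin in mouse bone marrow-derived dendritic cells, antigen-presenting cells recorded as CD11c-positive with high MHC class II. Per the series design, the cells had received lipopolysaccharide (LPS, a bacterial ligand of TLR4), and were pulsed or left unpulsed with the ovalbumin peptide OVA323-339. They were then cultured for 24 h with CD4-positive OT-II T cells, whose receptor recognises that peptide on MHC class II. The RNA-seq part held 3 activated and 3 non-activated libraries. The sample labels describe the activated cells as stimulated with LPS and the others as not stimulated, whereas the design text gives LPS to both and separates them by peptide. The terms activated and non-activated are therefore used here as in the sample titles. Transcripts that LPS is known to induce were plentiful in both groups: Ccl5 stood at 6994 ± 225 CPM (counts scaled to library size; SD, n = 3) in non-activated and 6233 ± 204 in activated cells, and Il1b at 525 ± 42.3 and 1317 ± 132. Ccl5 did not pass between groups. Il1b, Il12b and Il6, which LPS can also induce, were 2.51-fold, 7.89-fold and 3.17-fold higher in activated cells. No library known to lack LPS was measured, so these levels do not settle which description holds. Summed expected counts ranged from 21338012 to 27404937 per library. Another 4 samples, 2 activated and 2 non-activated, were labelled as ATAC-seq and were not analysed here.

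By the series design, the comparison of activated with non-activated cells asks what dendritic cells express after an encounter with T cells in the presence of their antigen. By the sample labels it would be a comparison of LPS stimulation, and which holds was not settled here. Activated cells held more RNA of several genes that act on T cells: the costimulatory receptor Cd40 was 7.42-fold higher (942 ± 52.1 against 127 ± 9.03 CPM, SD, n = 3), the shared IL-12 and IL-23 subunit Il12b 7.89-fold higher (1404 ± 311 against 178 ± 14.4) and the chemokine Ccl22 5.95-fold higher (18918 ± 893 against 3181 ± 538). Il23a, the other IL-23 subunit, rose from 0.648 ± 0.268 to 134 ± 71.7 CPM. Genes of the interferon gamma response rose in 24 of 26 measured members. In contrast, the chemokine receptor Cxcr4 fell from 142 ± 3.94 to 53.0 ± 11.3 CPM. The MHC class II gene H2-Ab1 did not pass, at 2780 CPM in activated and 2906 CPM in non-activated cells. In all, 3848 of 13946 tested genes (27.6%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2216 higher and 1632 lower in activated cells (1061 lower without non-activated replicate 2). Of these, 878 were at least 2-fold higher and 369 at least 2-fold lower.

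**Figure D1:**
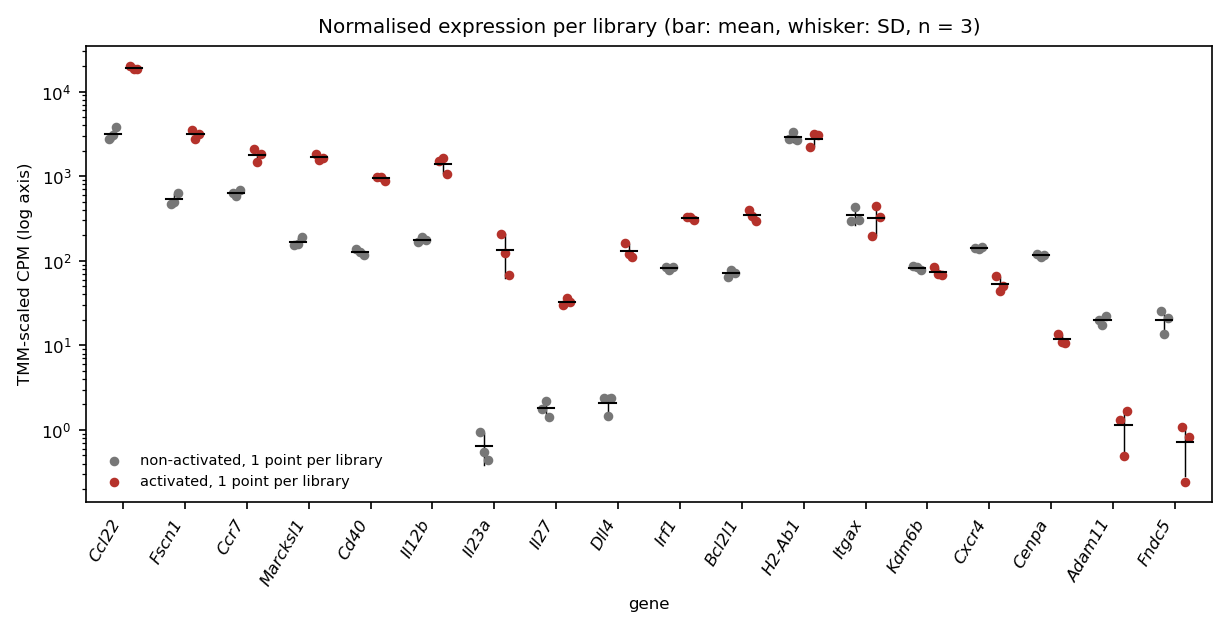
TMM-scaled CPM (log axis) of 18 genes in the 3 non-activated (grey) and 3 activated (red) libraries, with the mean as a bar and the SD as a whisker. The libraries of the groups do not overlap for Ccl22, Cd40 or Dll4, which were higher in activated cells, nor for Cenpa or Fndc5, which were lower, whereas those of H2-Ab1, Itgax and Kdm6b do.

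The list of genes that mark migratory mature dendritic cells rose, with 15 of 20 members higher, none lower and 5 not passing (15 higher when adjusted over the list alone), a median log2 fold change of 0.95 and a camera adjusted p of 2.02e-07. It was an adjusted p of 0.402 with an estimated correlation. Fscn1, which bundles actin in dendrites, went from 533 ± 83.8 to 3122 ± 377 CPM. Ccr7, the receptor that guides dendritic cells to lymph nodes, was 2.82-fold higher (1798 ± 294 against 638 ± 56.7 CPM). Marcksl1 was 10.0-fold higher and Nudt17 5.21-fold higher. Among costimulatory and coinhibitory molecules, 12 of 17 rose, 1 fell and 4 did not pass (12 and 1 when adjusted over the list alone), with a median of 0.57 and a camera adjusted p of 9.64e-05, which became an adjusted p of 0.402 with an estimated correlation. The TNF family ligand Cd70 (12.9-fold), the 4-1BB ligand Tnfsf9 (6.48-fold), Cd40 and the receptor Slamf1 (4.64-fold) were among those with the smallest adjusted p. The classical CD28 ligands moved less, Cd86 by 1.78-fold and Cd80 by 1.39-fold, and the PD-1 ligand Cd274 by 1.25-fold. The Cd80 call was lost without non-activated replicate 1 (edgeR adjusted p = 0.062) or 2 (0.0691), within a range of 0.00157 to 0.0691 over all alternatives. The Cd274 call was lost without any 1 of 5 libraries, activated replicate 1 being the exception (edgeR adjusted p 0.0879 to 0.151; 0.00321 to 0.151 over all alternatives). The member that fell was Tnfrsf9, the receptor of the Tnfsf9 product, at 681 ± 159 against 1200 ± 196 CPM. Its edgeR adjusted p of 0.0149 became 0.054 without non-activated replicate 3 (4.22e-05 to 0.054 over all alternatives).

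Dendritic cell cytokines rose in 16 of 19 measured genes, with 1 lower and 2 not passing (16 and 2 when adjusted over the list alone). The median log2 fold change was 1.15 and the camera adjusted p 3.81e-06, against an adjusted p of 0.402 with an estimated correlation. Il27 and Ebi3, which encode the subunits of IL-27, were 18.0-fold and 4.30-fold higher. Il23a and Il12b changed as given above, the macrophage growth factor Csf1 was 3.33-fold higher, and Il6 went from 116 to 368 CPM. Osm, which encodes oncostatin M, fell from 118 ± 9.57 to 87.4 ± 11.0 CPM, with an edgeR adjusted p of 0.0195 that became 0.0665 without non-activated replicate 1 (0.00156 to 0.0665 over all alternatives). Of 17 measured chemokines 6 rose, 0 fell and 11 did not pass (6 and 0 when adjusted over the list alone; median 0.70, camera adjusted p 0.0159, adjusted p 0.402 with an estimated correlation). Ccl22 and Ccl17 (2.53-fold), both ligands of CCR4, had the smallest adjusted p, followed by Cxcl3 (1.62-fold) and Ccl3 (2.09-fold). Chemokine receptors were mixed, with 4 of 13 higher, 1 lower and a camera adjusted p of 0.546: Ccr7, Cxcr5, Cxcr3 and Xcr1 rose and Cxcr4 fell. Cxcr3 rested on 88 counts against 8, and its log2 fold change went from 3.44 to 4.17 without non-activated replicate 1. The Cxcr5 call (1.55-fold) was lost without activated replicate 3 or non-activated replicate 1 or 2 (edgeR adjusted p 0.0518 to 0.0616; 0.00172 to 0.0616 over all alternatives). The Xcr1 call (2.24-fold) was lost without activated replicate 2 or non-activated replicate 2 or 3 (edgeR adjusted p 0.0508 to 0.0592; 0.00381 to 0.113 over all alternatives).

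Interferon gamma response genes gave the smallest list p in camera with the preset correlation, though not with an estimated one or in fry. Of 26 measured members 24 rose, 0 fell and 2 did not pass (24 and 0 when adjusted over the list alone), with a median log2 fold change of 1.24 and a camera adjusted p of 5.37e-12. It was an adjusted p of 0.402 with an estimated correlation. The transcription factor Irf1 was 3.92-fold higher (322 ± 13.1 against 82.1 ± 3.50 CPM), and the interferon-inducible GTPases Gbp5, Igtp and Tgtp2 were 3.26-fold, 4.07-fold and 7.75-fold higher. The type I interferon list rose in 14 of 21 members, with 0 lower and 7 not passing (14 and 1 when adjusted over the list alone; median 0.99, camera adjusted p 9.64e-05, adjusted p 0.785 with an estimated correlation). The fry test, which asks whether members move one way, did not call it (adjusted p = 0.0548, within 2.84e-09 to 0.883 over all alternatives). Isg15 (4.65-fold), Ifit1 (3.65-fold), Ifit2 (5.61-fold) and the RNA sensor Ifih1 (1.89-fold) had the smallest adjusted p. NF-kappaB and CD40 target genes rose in 15 of 22 members, with 2 lower and 5 not passing (16 and 2 when adjusted over the list alone; median 0.73, camera adjusted p 3.81e-06, adjusted p 0.402 with an estimated correlation). The survival gene Bcl2l1 (4.87-fold), the adhesion molecule Icam1 (2.82-fold), the inhibitor Nfkbie (2.30-fold) and Bcl3 (2.27-fold) were among them. The 2 that fell, the subunit Rel (194 against 385 CPM) and the kinase Map3k14 (86.9 against 252 CPM), belong to the pathway's activating arm. The JAK-STAT list was not called by camera (4 of 20 higher, 3 lower, camera adjusted p 0.962), though fry called it higher (fry adjusted p 0.004). Il2ra, encoding the IL-2 receptor alpha chain, went from 229 ± 22.2 to 707 ± 128 CPM. Stat5a, Socs1 and Socs3 were 2.09-fold, 1.73-fold and 1.73-fold higher. The receptor subunits Csf2rb and Csf2rb2, near-identical genes, and Osm were the members that fell (3150 against 4232, 1218 against 1720 and 87.4 against 118 CPM). Csf2rb lost its call without activated replicate 3 or any non-activated library (edgeR adjusted p 0.062 to 0.12; 0.00143 to 0.12 over all alternatives). The list's median of -0.02 and mean of 0.07 differed in sign, the camera direction being up.

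**Figure D2:**
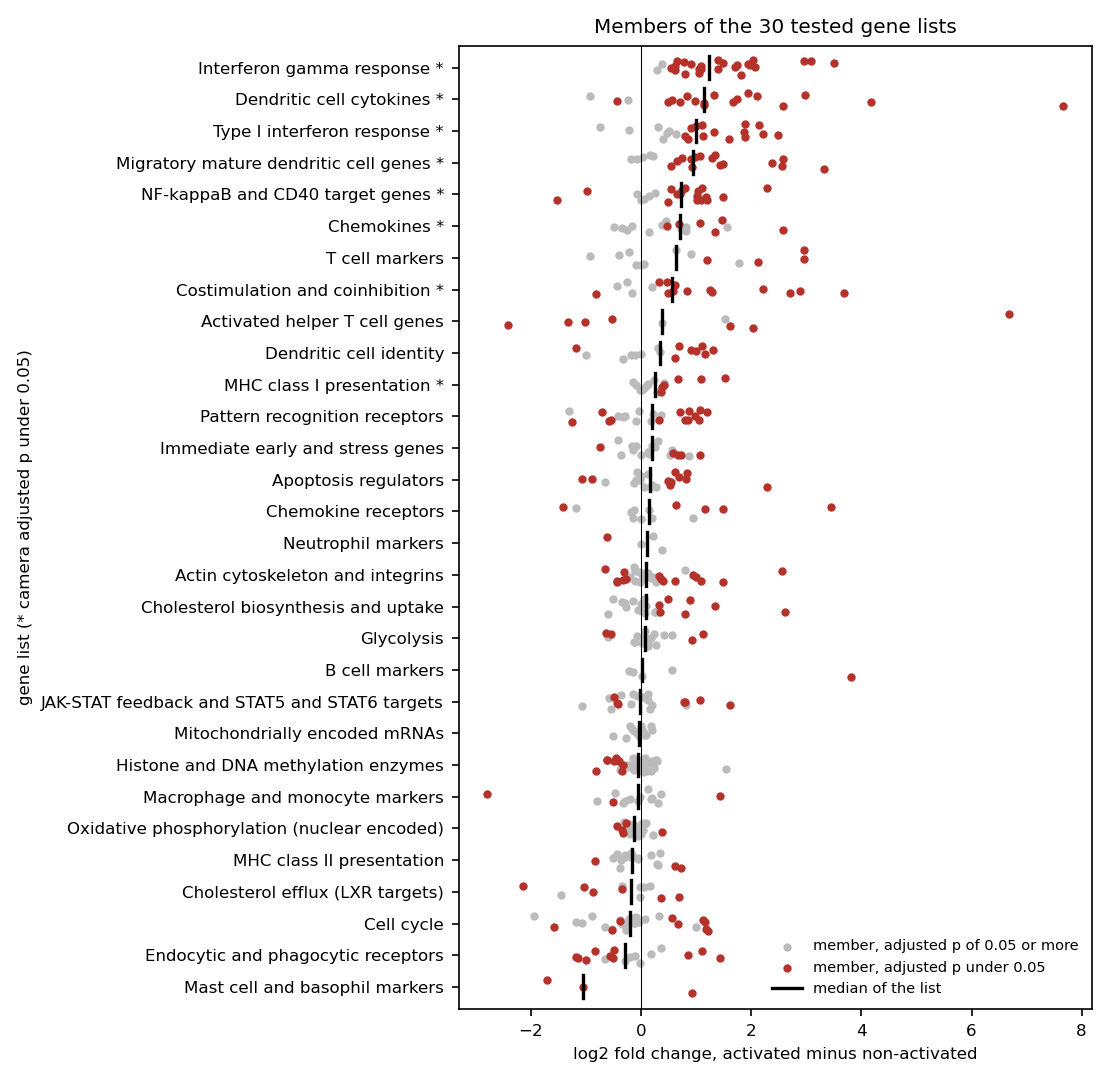
log2 fold change, activated minus non-activated, of every tested member of the 30 tested gene lists, with members past an adjusted p of 0.05 in red, others in grey and the list median as a black bar. The 8 lists with an asterisk, from interferon gamma response (median 1.24) to MHC class I presentation (median 0.26), passed camera with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p 0.402).

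Antigen presentation genes formed 2 lists, and the difference between them was not tested. In the MHC class I list 6 of 16 rose, 0 fell and 10 did not pass (6 and 0 when adjusted over the list alone; median 0.26, camera adjusted p 0.0264, adjusted p 0.43 with an estimated correlation). The proteasome activator subunit Psme2 (2.13-fold), the class I transactivator Nlrc5 (2.87-fold), the immunoproteasome subunit Psmb10 (1.58-fold) and Psme1 (1.28-fold) had the smallest adjusted p. Psme1 lost its call without both replicate 1 libraries (edgeR adjusted p = 0.0547; 0.00126 to 0.0547 over all alternatives). This list call was lost without activated replicate 2 (camera adjusted p = 0.0568) or non-activated replicate 3 (0.0898), within 0.00688 to 0.782 over all alternatives. In the MHC class II list 15 of 18 members did not pass and the list was not called (camera adjusted p 0.42). Rfx5 (1.65-fold) and Ciita (1.53-fold), regulators of class II transcription, rose and the endosomal protease Lgmn fell from 571 ± 67.6 to 320 ± 53.2 CPM. The Ciita call held only without activated replicate 1 among the leave-one-out fits, with edgeR adjusted p from 0.0591 to 0.0972 in the other 5 (0.000827 to 0.104 over all alternatives). Dendritic cell identity genes included 7 of 15 higher and 1 lower (camera adjusted p 0.0941), with the transcription factors Irf4 (2.46-fold) and Zbtb46 (2.00-fold), the endocytic receptor Ly75 (2.15-fold) and Sirpa (1.61-fold) higher and the lectin Clec10a lower (1.55 against 3.51 CPM). Itgax, which encodes CD11c, did not pass (log2 -0.10 ± 0.27, SE; edgeR adjusted p = 0.817).

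Receptors for microbes and for uptake moved both ways. Of 22 pattern recognition receptors 9 rose and 4 fell (camera adjusted p 0.476), with Cgas (2.09-fold), Nod1 (2.06-fold) and Tlr1 (1.73-fold) higher. Tlr13, a sensor of bacterial ribosomal RNA, was lower by counts (log2 -0.58 ± 0.09, SE), a direction that turned on the deposited TPM (log2 0.48, limma adjusted p = 0.639; 1.36e-07 to 0.647 over all alternatives). The others that fell were Tlr4, the receptor of LPS (127 against 186 CPM), and the nucleic acid sensors Tlr8 (4.42 against 7.28) and Tlr9 (10.9 against 25.9). The Tlr8 call too was lost on the deposited TPM, where its log2 fold change went from -0.72 to -0.10 (limma adjusted p = 0.783; 0.00207 to 0.783 over all alternatives). Of 17 endocytic and phagocytic receptors 3 rose and 7 fell (camera adjusted p 0.179), with the scavenger receptors Cd36 (428 against 768 CPM) and Scarb1 (29.9 against 44.3 CPM) lower and the efferocytosis receptor Mertk 2.72-fold, Ly75 2.15-fold and Axl 1.80-fold higher. The Axl call held only without activated replicate 1 among the leave-one-out fits (edgeR adjusted p 0.0514 to 0.124 in the other 5; 0.000661 to 0.133 over all alternatives). In the actin and integrin list 9 of 32 rose and 6 fell (camera adjusted p 0.226), with the smallest adjusted p for Fscn1, Icam1, the Cdc42 activator Dock8 (2.12-fold) and the integrin Itgal (1.92-fold). The 2 cytoplasmic actins moved apart, Actb from 3663 ± 145 to 7281 ± 759 CPM and Actg1 from 4969 ± 221 to 3658 ± 123 CPM, and kept these directions under each scaling tried. They are near-identical in coding sequence, and their expected counts are uncertain to the extent that reads were shared.

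Metabolic and cell cycle lists were not called. Glycolysis had 2 of 20 higher and 2 lower (camera adjusted p 0.677): the hexokinases Hk2 (2.19-fold) and Hk1 (1.90-fold) rose, while Aldoa and Gpi1 fell to 1344 and 668 CPM from 1971 and 1045 CPM. Gpi1 lost its call without non-activated replicate 3 (edgeR adjusted p = 0.0517; 0.000116 to 0.0517 over all alternatives). Nuclear-encoded oxidative phosphorylation genes had 1 of 26 higher and 4 lower (median -0.12, camera adjusted p 0.066). Ndufa4 was 1.31-fold higher, and Cox4i1, Sdhd, Ndufb5 and Ndufb8 were lower (0.742, 0.783, 0.797 and 0.823 times the non-activated level). The Ndufa4 call was lost without non-activated replicate 1 or 3 (edgeR adjusted p = 0.0581 and 0.0517; 0.00881 to 0.0906 over all alternatives). Ndufb8 lost its call without non-activated replicate 1 or 2 (edgeR adjusted p = 0.0857 and 0.0794; 0.00664 to 0.0857 over all alternatives). Ndufb5 lost it without activated replicate 3 or non-activated replicate 2 or 3 (edgeR adjusted p = 0.0639, 0.0966 and 0.0698; 0.00842 to 0.0966 over all alternatives). Among cholesterol synthesis and uptake genes 7 of 22 rose and 0 fell (camera adjusted p 0.271), with Idi1 2.53-fold higher. Of 12 LXR targets 2 rose and 4 fell (camera adjusted p 0.359). The desaturase Scd1 fell from 11.6 to 2.63 CPM, Mylip, Smpdl3a and Abcg1 were 0.485, 0.543 and 0.790 times the non-activated level, and Nr1h3 and Lpcat3 were 1.61-fold and 1.28-fold higher. Nr1h3 lost its call without both replicate 1 libraries (edgeR adjusted p = 0.0716; 0.00251 to 0.0716 over all alternatives). Abcg1 lost its call without non-activated replicate 1 or 2 (edgeR adjusted p = 0.0801 and 0.0916; 0.00254 to 0.0916 over all alternatives). Lpcat3 kept its call only without non-activated replicate 1 (edgeR adjusted p 0.0595 to 0.123 in the other 5 fits; 0.0222 to 0.198 over all alternatives). Cell cycle genes had 6 of 29 higher and 3 lower (camera adjusted p 0.514). Mki67 and the helicase subunit Mcm3 were 2.19-fold and 2.32-fold higher. Top2a fell from 25.6 to 8.52 CPM, Mcm6 from 41.6 to 28.9 and Mcm7 from 13.6 to 10.5. Mcm6 lost its call without non-activated replicate 3 (edgeR adjusted p = 0.0646; 0.00209 to 0.0646 over all alternatives). Mcm7 lost its call without any 1 of the libraries but activated replicate 1 (edgeR adjusted p 0.0758 to 0.123; 0.0236 to 0.172 over all alternatives). The cell cycle median was -0.20 and camera's direction down, whereas fry's was up. Histone and DNA methylation enzymes had 0 of 41 higher and 8 lower (camera adjusted p 0.3). Setd7, Ezh1, Tet2 and Smyd3 had the smallest p (0.647, 0.709, 0.649 and 0.569 times the non-activated level). Smyd3 lost its call on the deposited TPM (limma adjusted p = 0.0586; 0.00012 to 0.0586 over all alternatives). The H3K27 demethylase Kdm6b stood at 73.9 against 82.3 CPM (edgeR adjusted p = 0.298), and passed only without activated replicate 1 (0.0384, the lowest over all alternatives, with 0.519 the highest). Apoptosis regulators had 8 of 21 higher and 2 lower (camera adjusted p 0.16), with Bcl2l1 and Bcl2a1d (1.79-fold) higher and the pro-apoptotic Pmaip1 and Bbc3 lower (58.4 against 108 and 14.4 against 30.3 CPM). Of 19 immediate early and stress genes 4 rose and 1 fell (camera adjusted p 0.42). Hspa1b (2.11-fold), Hsp90aa1 (1.65-fold), Ier2 (1.59-fold) and Ier3 (1.49-fold) rose and Fos fell (24.5 against 41.4 CPM). Ier3 lost its call without activated replicate 1 or 3 or non-activated replicate 2 or 3 (edgeR adjusted p 0.0542 to 0.126; 0.000998 to 0.126 over all alternatives). By edgeR 0 of 13 mitochondrially encoded mRNAs passed in either direction (camera adjusted p 0.526), with 0 higher and 1 lower at an unadjusted p under 0.05, and mt-Co1 stood at 7631 against 9184 CPM. Together these mRNAs and other mitochondrially encoded RNA took 1.80% to 2.12% of counts in activated and 2.20% to 2.56% in non-activated libraries. Ribosomal protein genes took 1.29% to 1.49% and 1.73% to 1.98%, so that the groups overlapped in neither share, as chance gives for 10% of measures with 3 against 3. For the lists of this and the preceding paragraph and those below, the counts changed by at most 1 in either direction when adjusted over the list alone. Where a list had 0 lower members, an unadjusted edgeR p under 0.05 gave 2 lower in the cholesterol list, 1 each in the type I interferon and T cell lists and 0 in the interferon gamma, migratory, chemokine, MHC class I and B cell lists. Where a list had 0 higher members, it gave 4 higher methylation enzymes and 0 neutrophil markers.

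No tested list of markers of other cell types was called by camera with the preset correlation. T cell markers had 4 of 13 higher and 0 lower (camera adjusted p 0.349), the kinase Lck going from 0.999 ± 0.279 to 4.37 ± 0.692 CPM, with Sh2d2a, Zap70 and Cd247 the others. Without activated replicate 1 the log2 fold change of Sh2d2a went from 2.96 to 2.10, and Zap70 and Cd247 no longer passed (edgeR adjusted p = 0.113 and 0.135). Both also lost their calls without non-activated replicate 2 or 3 (Zap70 0.102 and 0.111, Cd247 0.122 and 0.126), and Cd247 without activated replicate 2 or 3 (0.0501 and 0.0669), by edgeR adjusted p, within ranges over all alternatives of 0.00145 to 0.113 and 0.00588 to 0.135. The log2 fold change of Zap70 went from 2.95 to 3.73 without non-activated replicate 1. Cd3e was too low to test, with 1.86 raw CPM in activated replicate 1 and 0.16 to 0.40 raw CPM in the other 5 libraries. Il2 had 255 counts in activated and 2 in non-activated libraries, a ratio of 126 (95% exact interval 34.5 to 1050, counting error only), and 232 of the 255 came from activated replicate 1. Its edgeR adjusted p of 0.0187 rose to between 0.0612 and 0.0781 when any non-activated library was left out (0.000246 to 0.0781 over all alternatives). Without activated replicate 1 it was 0.0213, and the ratio was 18.1 (23 against 2 counts, interval 4.47 to 158). Both non-activated counts came from non-activated replicate 3, without which Il2 was at least 57-fold higher against a floor of 3 counts over the group. Ifng, with 45 against 2 counts, was not tested. The activated helper T cell list had 3 of 9 higher and 4 lower (camera adjusted p 0.962), with Il2, Il2ra and Il13 higher and Tnfsf8, Icos, Tnfrsf18 and Pdcd1 lower (21.1 against 42.5, 5.10 against 12.9, 7.94 against 11.5 and 0.356 against 2.01 CPM). Tnfrsf18 lost its call without activated replicate 3 or non-activated replicate 2 or 3 (edgeR adjusted p 0.0637 to 0.0892; 0.00957 to 0.0892 over all alternatives). Pdcd1 kept its call only without activated replicate 1, where its log2 fold change went from -2.42 to -4.15 (edgeR adjusted p 0.0605 to 0.151 in the other 5 fits; 0.00325 to 0.151 over all alternatives). B cell markers had 1 of 5 higher and 0 lower (Cd79b, 137 against 10 counts; camera adjusted p 0.656), with a log2 fold change of 3.81 that went to 4.91 without non-activated replicate 3. Neutrophil markers had 1 of 4 lower and 0 higher (Mmp8, 118 against 182 CPM; camera adjusted p 0.962). Macrophage and monocyte markers had 1 of 15 higher and 2 lower (Mertk higher and Fcgr1 among the lower; camera adjusted p 0.486). The Mmp8 call was lost without activated replicate 3 or non-activated replicate 2 (edgeR adjusted p = 0.0526 and 0.0774; 0.000515 to 0.0774 over all alternatives). The Fcgr1 call was lost without activated replicate 1 or 3 (0.0517 and 0.0516) or non-activated replicate 1 or 2 (edgeR adjusted p = 0.128 and 0.13; 0.00533 to 0.13 over all alternatives). Of 3 measured mast cell and basophil genes Gata2 and Kit fell and Hdc rose (camera adjusted p 0.369). Of the NK cell list only Klrk1 and Klrd1 were tested, at 9.95 against 20.1 and 0.234 against 0.863 CPM, neither passing. Neutrophil markers differed in sign between median (0.11) and mean (-0.01), with camera's direction down and fry's up.

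Both replicate 1 libraries stood apart on the second principal component, which took 17.7% of the variance against 59.0% for the component that separated the groups. In both of them the T cell receptor alpha constant gene Trac reached 7284 (activated) and 7582 raw CPM (non-activated), against 2.75 to 27.3 in the other 4 libraries (edgeR adjusted p = 1 between groups). Without both replicate 1 libraries, an alternative added after the Trac level was seen, 3274 genes passed, of which 2914 were among the 3848.

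Among the 12 well-measured genes with the highest log2 fold change were Fam131c, Nccrp1, Il23a, Dll4, Adamts4, Erbb2, Dact3, Oaf, Bmp1 and Cdo1. Dll4, a ligand of Notch receptors (chromosome 2, 119325784 to 119335666, GRCm38), was 62.5-fold higher (131 ± 26.4 against 2.09 ± 0.534 CPM; edgeR adjusted p = 1.99e-06). Fam131c had 1034 counts against 1, a ratio of 1020 (95% exact interval 183 to 40400, counting error only). That count came from non-activated replicate 1, without which Fam131c was at least 220-fold higher against a floor of 3 counts over the group. The 12 strongest falls included Fndc5, F5, Adam11, Cenpa, Npr1, Hepacam2, Tg, Mical2, Ndrg4, Dpysl5 and Fgf1. The centromere histone gene Cenpa (chromosome 5, 30666877 to 30674837) fell from 116 ± 4.84 to 11.8 ± 1.61 CPM (edgeR adjusted p = 1.99e-06), and Npr1, a receptor of natriuretic peptides, from 98.0 ± 7.19 to 10.8 ± 5.45 CPM. Fndc5 and Adam11 were 26.8-fold and 16.8-fold lower. Leaving out activated replicate 1 moved the log2 fold changes of F5 from -4.63 to -6.07, of Tg from -3.07 to -3.78 and of Fgf1 from -2.61 to -3.23, each still called.

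The split of calls depended on scaling: 57.6% of the changed genes were higher in activated cells with TMM factors and 44.1% with library totals only (1792 higher, 2274 lower), which shifted the median log2 fold change of all genes to -0.07. On the TPM scale with a pseudocount of 1, fold changes of low genes were smaller, as for Il23a (log2 6.40 against 7.67) and Fndc5 (-3.12 against -4.74), and 2569 genes passed limma.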

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

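The alternative without both replicate 1 libraries, and the blocked camera with an estimated correlation, were chosen after the data were seen. None of the 3848 calls was turned and still called in any alternative fit. The changed genes, 3848 in the main test, came to 2516 with limma on log2(TPM + 0.1), 2116 at an adjusted p under 0.01 and 1247 with a log2 fold change of at least 1. For genes higher in activated cells, 2216 in the main test, limma gave 1467 with log2(TPM + 1) and 1440 with log2(TPM + 0.1), the stricter p 1322 and the fold limit 878. For lower genes, 1632 in the main test, these were 1076 with log2(TPM + 0.1), 794 and 369. The stricter limits lower a count by their construction; for TPM the cause was not tested. Leaving out each library in turn gave 2679 to 3629 changed genes, 1586 to 1956 higher and 1061 (without non-activated replicate 2) to 1673 lower. The replicate block gave 5184 changed genes, 2787 higher and 2397 lower, kept 3831 of the 3848 and changed no call of the 185 named genes tested under it or of the 8 lists. DESeq2 gave 4135, limma-voom 3825, upper-quartile factors 3915, no filter 3999 and the omission of T cell list genes 3861.

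The 8 lists called higher were 0 with an estimated correlation, with or without the block, 12 with fry (7 of the 8 among them), and 7 to 8 when a library was left out. The others in fry were actin and integrins (fry adjusted p 0.00103), dendritic cell identity (0.00113), apoptosis (0.00189), JAK-STAT (0.004) and pattern recognition receptors (0.0268). Fry as used here asks whether members move one way, whatever other genes do, and camera whether they do so more than other genes. The 0 lists called lower became 1 with library totals only, with T cell list genes left out and, within a range of 0 to 1, without activated replicate 2 or non-activated replicate 3, each time oxidative phosphorylation; fry gave 1, the mast cell and basophil list. The cause was not tested. Of 182 named genes that passed, 142 stayed past the threshold in the same direction under every alternative fit with a value, and 35 lost the call when some library was left out. Tlr13 turned with TPM (log2 0.483 with a pseudocount of 1 and 0.484 with 0.1, from -0.58), and the cause was not tested. H2-Ab1 and Itgax, which never passed, ranged from -0.17 to 0.063 and from -0.413 to 0.135 over the fits without 1 library, the highest without activated replicate 1, turning also to 0.033 and 0.098 without non-activated replicate 2, and to 0.02 and 0.032 without both replicate 1 libraries. Depth limits genes such as Cd3e, Ifng and Il2, with 14, 2 and 2 counts over the non-activated libraries.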

Other observations

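The gene families, the chromosome test and the tests of T cell transcripts in this part were chosen after the values were seen, as was the count over splits of the libraries. A first form of the T cell list tests, limited to genes low in the non-activated libraries, was dropped because that limit bears on the comparison.

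Some families of contact and guidance molecules changed member by member, 7 families in all being tried and none passing as a set. Of 7 Notch ligands and receptors Dll4 and Jag1 rose (62.5-fold and 2.42-fold) and Jag2, Dll1 and Notch3 fell (1.85 against 6.35, 0.197 against 0.734 and 0.128 against 0.616 CPM; camera adjusted p = 0.592). Dll1 and Notch3 lost their calls without activated replicate 1 (edgeR adjusted p = 0.0511 and 0.058) or non-activated replicate 3 (0.0597 and 0.072), within 0.0117 to 0.0842 and 0.014 to 0.072 over all alternatives. Of 13 Wnt ligands and Frizzled receptors 7 rose and 2 fell (camera adjusted p = 0.276). Wnt3 had 377 counts in activated and 0 in non-activated libraries, at least 124-fold higher against a floor of 3 counts over the group, while Wnt9b had 180 against 2 counts, a ratio of 88.9 (95% exact interval 24.3 to 740). Both counts came from non-activated replicate 3, without which Wnt9b was at least 40.2-fold higher against the same floor. The annotations of these neighbours overlap and reads could not be assigned by strand. The Wnt receptor Fzd4 went from 0.307 ± 0.03 to 9.24 ± 5.31 CPM, and its annotation too overlaps another gene, Tmem135. Wnt11 (259 against 567 counts) lost its call without non-activated replicate 3 (edgeR adjusted p = 0.0501; 0.000422 to 0.0501 over all alternatives). Fzd6 (10 against 49 counts) kept its call only without activated replicate 1, where its log2 fold change went from -2.22 to -3.22 (edgeR adjusted p 0.0564 to 0.0793 in the other 5 fits; 0.00968 to 0.0793 over all alternatives). Of 17 semaphorins and plexins 7 rose and 3 fell (camera adjusted p = 0.353), with Sema7a at 1867 ± 187 against 457 ± 47.7 CPM and Sema6d at 179 against 61.3 higher. Lower were Plxnc1, a receptor of the Sema7a product (141 ± 26.2 against 261 ± 23.7), Sema4f (2.18 against 9.39, with a log2 fold change of -2.08 that went to -2.82 without activated replicate 1) and Plxna3 (1.41 against 2.69). Plxna3 lost its call whichever library was left out (edgeR adjusted p 0.0504 to 0.124; 0.0248 to 0.153 over all alternatives).

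In the plasminogen activation family (camera adjusted p = 0.275) the tissue activator Plat was higher (291 ± 79.1 against 13.3 ± 1.59 CPM). Dual-specificity phosphatases, many of which inactivate MAP kinases, had 7 of 20 higher and 4 lower (camera adjusted p = 0.52), Dusp2 being 11.3-fold higher and Dusp5, Dusp4, Dusp3 and Dusp11 lower (82.9 against 246, 37.1 against 63.4, 86.9 against 110 and 83.4 against 101 CPM). Dusp11 kept its call only without activated replicate 1 (edgeR adjusted p 0.054 to 0.116 in the other 5 fits; 0.0179 to 0.116 over all alternatives). Among 8 members of solute carrier family 7, amino acid transporters, Slc7a6, Slc7a5, Slc7a1, Slc7a2 and Slc7a8 rose (2.80-fold, 1.99-fold, 1.86-fold, 1.76-fold and 1.41-fold) and Slc7a7 fell (10.3 against 24.3 CPM; camera adjusted p = 0.276). Slc7a8 kept its call only without non-activated replicate 1 (edgeR adjusted p 0.0578 to 0.105 in the other 5 fits; 0.00276 to 0.105 over all alternatives). Of 13 TNF superfamily ligands 6 rose and Tnfsf8, Tnfsf14 and Tnfsf13b fell (21.1 against 42.5, 1.40 against 3.38 and 5.44 against 12.7 CPM; camera adjusted p = 0.353). Tnfsf14 lost its call without non-activated replicate 2 (edgeR adjusted p = 0.0606; 0.00128 to 0.0606 over all alternatives) and Tnfsf13b without non-activated replicate 3 (edgeR adjusted p = 0.0582; 0.000168 to 0.0582 over all alternatives). None of the called members of the 7 families turned under library totals, upper-quartile or DESeq2 scaling.

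The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. By edgeR the real split gave 3848 changed genes and the highest of the other splits 0 (5507 against 72 to 570 genes at an unadjusted p under 0.05), so 1 split of the 10 was as large. The real split parts all 3 replicate pairs, as do 3 of the others, which gave 0 changed genes (72 to 127 unadjusted); those others put 1 or 2 activated libraries with non-activated ones.

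T cell receptor transcripts marked both replicate 1 libraries, activated or not. Trac reached 7284 and 7582 raw CPM there, 99.98% and 99.99% of alpha variable-segment counts fell on Trav14 (144838 and 143555 counts), whose near-identical copies shared reads, and 98.2% and 98.5% of beta ones on Trbv12. Carried-over T cells are argued against: Cd3d, Cd3e and Cd3g summed to at most 0.0501% of Trac in these libraries, and to 0.54 raw CPM in the non-activated one. A candidate explanation is a rearranged receptor transcribed in the cells of the marrow donor, such as an OT-II transgene, which uses these segment families. The share on 1 alpha family, 99.98% at the lower, is what it needs, but it is not particular to these libraries (97.52% to 100% of 52 to 438 counts in the other 4) and T cells of 1 clone would share it, and the donor's genotype stays untested.

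Other genes also set both replicate 1 libraries apart, compared on CPM with a small offset added and receptor genes left out. By over 4-fold from both other replicates in both groups 5 differed. Chil1 (348 and 295 CPM against at most 0.73), Ctse and Gm48274 were higher and Rbp4 and Gm47283 lower. Among genes over 2-fold apart with the offset, Steap3 (activated 8.33 against at most 2.01, non-activated 23.1 against at most 4.50 CPM) would differ so too without it. So would Lrmda (0.74 and 1.03 against at least 4.99) and Gm29253 (0 and 0 against at least 0.98 CPM). Chil1 and Ctse lie on chromosome 1 (134182156 to 134190031 and 131638314 to 131675507, GRCm38). The chromosome test was run in 3 forms, each with that offset. First was over 4-fold with receptor genes included (2 of 8 genes on chromosome 1, Fisher exact adjusted p 0.491 over 20 chromosomes). In it chromosome 14 passed through 3 receptor genes alone (Fisher exact adjusted p 0.0358). The other forms left receptor genes out, at over 4-fold (2 of 3 genes, Fisher exact adjusted p 0.192) and over 2-fold (5 of 28 genes, 0.41). A donor or strain difference on chromosome 1 may be involved, but none of the 3 forms passed for that chromosome. The over 4-fold forms depend on the offset, since Steap3 lies on chromosome 1 and Lrmda on chromosome 14, and no form was run without it. At over 2-fold the chromosome 1 genes were Wdfy1 (from 79702262) and Steap3, Ctse, Slc26a9 and Chil1 (from 120226414 to 134190031), a grouping that was not tested. Whether a library or day difference of replicate 1 was the whole cause could not be decided by the chromosome test. Once receptor genes were left out 0 chromosomes held more than their share, but the genes are too few and whole chromosomes were compared.

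Activated replicate 1 held traces of T cell transcripts beyond the receptor. Of 41 T cell list genes with a count (receptor constant genes left out), of which 13 averaged at least 1 CPM in the non-activated libraries, 30 were highest in this library (exact binomial p = 2.07e-15, one-sided, against 1 in 6, genes not being independent), among them Il2 at 8.46, Cd6 at 6.64 and Sh2d2a at 6.22 raw CPM. RNA of carried-over T cells in this library could give this. The cells are labelled as CD11c-positive with high MHC class II, a selection that would lower the share of T cells. How far it did so was not measured. Xist, an RNA of female cells, also stood at 4.83 CPM in this library against at most 0.98 in the others. The Y-linked Ddx3y stood at 73.4 to 109 CPM in all 6. A change of the cultured cells shared by the 3 activated libraries is not excluded for part of them, since 14 of the 41 were also higher in both other activated libraries than in all non-activated ones (exact binomial p = 2.55e-05, one-sided, against 1 in 10). Small numbers of T cells in those libraries could give that too, and the counts do not decide. The references of 1 in 6 and 1 in 10 take no gene to differ between groups or libraries. Among all tested genes, however, 27.6% passed between the groups. The share of all genes meeting either rule was not counted. The binomial p-values therefore do not set T cell list genes apart from other genes.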
